A study of Drosophila melanogaster with 12 samples.

How the data were processed

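RNA was measured in whole heads of adult *Drosophila melanogaster* of the *y w* strain. Per the labels, flies lived in cycles of 12 h light and 12 h dark for 3 days before the harvest. They were then frozen every 4 h through 1 more such day (LD) and through the next day in constant darkness (DD). Heads, about 100 to 200 per sample, were separated from broken frozen bodies on sieves, and labelled cRNA was made from about 25 µg of RNA. Each of the 12 samples was hybridised to 1 array, so each hour of each day was measured 1 time and each day holds 6 arrays. Hours count from lights-on in LD and from the corresponding subjective lights-on in DD, at 2, 6, 10, 14, 18 and 22 h. No label says that samples of a day came from separate cultures, so p-values measure the spread of these arrays around the fitted curves. The LD day always came first, and light regime, elapsed time and age of the flies therefore moved together.

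The deposited values are RMA summaries per probe set, per the submitters' processing notes, which give no version. That they are on a log2 scale was read from the values, which the deposited table holds between 1.774 and 13.771 with array medians of 5.49 to 5.53. Which arrays RMA normalized together is not given in the sources used here. RMA quantile normalization gives every array nearly the same overall distribution, so a global change of RNA amount cannot be seen. The table held 14010 probe sets and no missing value. The 44 control probe sets were left out of all tests, which leaves 13966. Because the values were already logarithmic, no pseudocount was used and an alternative with one was not run.

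Probe sets were named through the platform annotation, with symbols updated by gene identifier through a table of reference genes on the Release 6 plus ISO1 MT assembly. Of the tested probe sets, 12443 name 1 gene, 327 name several and 1196 name none. No build is stated for the array, so no coordinates are given. The 10844 genes were each represented by the probe set with the highest mean over the 12 arrays, and other probe sets of a named gene are reported where they differ. The number of arrays, not counting error, limits the precision.

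Rhythms were fitted with limma 3.58.1 in R 4.3.3. The main model held a day term and cos and sin terms of a 24 h period over all 12 arrays, with a moderated F test of the cos and sin terms. Rhythm in LD, rhythm in DD and their difference came from a model with separate terms per day and 1 shared estimate of the spread. The shift between days was the day coefficient of the main model, coded LD minus DD. The lights-on effect was the coefficient of an indicator added to the main model, which is 1 on the 3 lit arrays and 0 on the 9 dark ones. Because the model also holds the day and the shared 24 h curve, this coefficient follows only in part how LD minus DD differs between lit and dark hours. It weights the hours and days unequally and also takes up departures of the profiles from the shared curve. It is not a direct comparison of lit and dark arrays at the same hours, whose plain means were computed beside it after the values were seen. Adjusted p-values follow Benjamini-Hochberg over all 13966 probe sets, with a threshold of 0.05. Ranges are peak to trough of the fitted curve, and their standard errors come from the moderated variance, with 8 residual degrees of freedom in the main model, 6 in the model with separate days and 7 with the light indicator.

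Before the data were examined, 28 gene lists were fixed from general knowledge, without the literature at hand: clock, output, sensory, neural, metabolic, defence and housekeeping genes, and markers of other body parts and sexes that sieving or the mixture of flies could bring in. The 27 lists with 3 or more measured members were tested. Members of some lists were taken by symbol pattern, and 1 gene that matched the ribosomal pattern without encoding a ribosomal protein was left out. The rhythm of a list mean was tested by exact permutation of the arrays within each day over all 518400 orders, with numpy 2.4.6 in Python 3.11.15. Shifts of lists were tested with camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives. Marker levels of the days were compared by exact permutation with scipy 1.17.1.

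Genes named in the text follow a rule also fixed before the data were examined: all measured core clock genes, up to 15 further called genes for rhythm, up to 10 per direction for a shift, the 5 smallest p-values (per direction for a shift) where fewer than 5 genes passed, and up to 4 members with the smallest p from each list. Exceptions are named as such. Alternatives were quantile normalization of the log2 values, only probe sets with a mean above the median, a trended robust prior, leaving out each array, a 12 h component, a linear trend, an exact test per probe set, each day alone, and the hour as a block. A body-marker score (mean of the midgut, male accessory gland and testis lists) as a covariate, and leaving out the DD 2 h and LD 22 h arrays together, were added after seeing the data.

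The fits were tested on simulated data with the real means and residual spreads over 13966 probe sets, 200 of them changed. For a rhythm over both days with a range of 1 log2 unit, 88.0% of the changed probe sets were called, with 7 calls among the others. For a rhythm in 1 day of that range, 65.5% were called in LD and 61.5% in DD, and for the rhythm difference 20.0%. At a range of 2 log2 units the rhythm difference was called for 87.5%. For a shift of 1 log2 unit, 97.5% were called between days and 83.5% for lights-on. With no effect simulated, no comparison gave a call. The noise was drawn for each probe set on its own, so deviations that many genes of an array share were not simulated. With the real values, other orders or splits of the arrays gave up to 15 calls in LD, 166 in DD and 1122 for lights-on. The simulated rates may therefore not hold for these arrays. The exact test gave p under 0.05 in 5.2% of 1000 profiles with no rhythm.

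Arrays of the same hour were also checked for shared deviations from their day means. Their correlations ran from -0.378 to 0.504 and were under 0.1 for 2 of the 6 hours, so the hours were not treated as pairs. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3.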

Results

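Transcript levels in heads of adult fruit flies were followed through 1 day of light and dark (LD) and the following day in constant darkness (DD). The schedule asks which transcripts cycle with the time of day, whether the cycle continues without light, and which transcripts differ between the days or with light itself. Each of the 12 arrays is a single sample of heads, taken every 4 h, with 6 arrays per day and no repeated hour. Levels are log2 RMA values of 13966 probe sets, and array medians lay between 5.49 and 5.53. On 11 of the arrays the median correlation with the other arrays was 0.982 or higher. On the DD 2 h array it was 0.959.

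Among the transcripts rhythmic over both days were 5 genes of the circadian clock, and *vri*, a dimmer probe set of *tim* (5.71-fold) and *Pdp1* gave the 3 smallest p-values. The transcript of *tim*, a clock repressor whose protein is destroyed in light, cycled 7.73-fold from peak to trough with its peak at 15.7 h ± 0.415 (SE, 12 arrays), early in the night. Its partner *per* cycled 2.47-fold with a peak at 14.7 h ± 0.449, and the clock transcription factor genes *vri* and *Pdp1* cycled 4.61-fold and 2.82-fold with peaks at 13.7 h ± 0.304 and 16.0 h ± 0.354. *Clk*, which encodes the activator of these genes, ran in the opposite phase: it cycled 3.04-fold and peaked at 1.75 h ± 0.432, after lights-on. The adjusted p-values of limma's moderated F test were 0.00895 for *tim*, 0.0139 for *per*, 0.00321 for *vri*, 0.00686 for *Pdp1* and 0.012 for *Clk*.

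**Figure D1:**
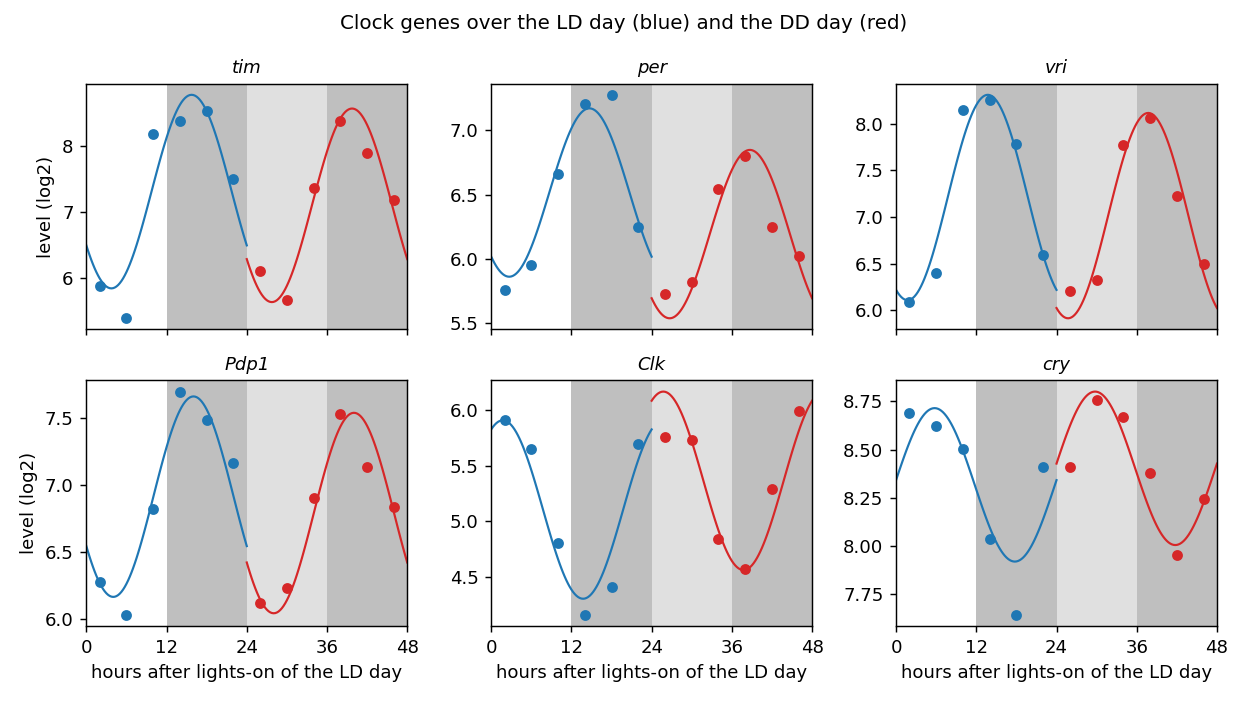
Levels (log2) of 6 clock genes against hours after lights-on of the LD day, 1 array per point, with the fitted 24 h curve that shares its range and phase between the LD day (blue) and the DD day (red). White is light, dark grey is night or subjective night and light grey is the subjective day in darkness. The curves of *tim*, *per*, *vri* and *Pdp1* peak between 13.7 and 16.0 h of each day and that of *Clk* at 1.75 h.

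Of the 16 measured core clock genes these 5 passed over all probe sets, and 7 passed when adjusted over the list alone, with *cry* and *tws* added. *cry*, which encodes the blue-light receptor of clock cells, had a range of 0.80 ± 0.14 log2 units with a peak at 5.76 h and an adjusted p of 0.152. *tws*, a phosphatase subunit that acts on clock proteins, had a range of 0.56 ± 0.13 with an adjusted p of 0.372. *cyc*, whose protein is the partner of CLK, had a range of 0.17 ± 0.07 and an adjusted p of 0.672. The remaining members gave ranges of 0.19 ± 0.11 for *cwo*, 0.14 ± 0.13 for *dco*, 0.13 ± 0.12 for *jet*, 0.04 ± 0.19 for *slmb*, 0.39 ± 0.17 for *CkIalpha*, 0.07 ± 0.11 for *Pdf*, 0.32 ± 0.11 for *Pdfr* and 0.39 ± 0.13 for *wdb*. Another probe set of *cwo* gave 1.89-fold with an adjusted p of 0.14, and a dim probe set of *tim* gave 1.12-fold with an adjusted p of 0.714. The mean of the core clock list cycled by 0.41 log2 units with a peak at 14.8 h, and its exact permutation p was 0.000579 (adjusted 0.0156 over 27 lists). It was the single list to pass, and with the body-marker score taken out of the list means none passed. The core clock list then kept a range of 0.30 log2 units and its peak at 14.8 h, with an exact p of 0.00995 (adjusted 0.269). The score was taken out without day or hour terms, and in DD it ran from 1.91 at 2 h to -0.75 at 18 h. This step can therefore also remove rhythm of a list, and the loss does not show that the rhythm came from body RNA. With the score inside the fit of each probe set 19 were rhythmic, 16 of them among the 20 of the main fit.

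Outside the core clock, genes of several kinds were rhythmic. *Ugt35B1*, a UDP-glycosyltransferase, cycled 6.90-fold and *phu*, an alkaline phosphatase, 5.47-fold, with morning peaks at 3.61 h ± 0.406 and 2.57 h ± 0.409. The dipeptidase gene *Dip-B* (1.90-fold, 2.50 h) and the glutathione transferase gene *GstZ2* (1.92-fold, 5.79 h) also peaked in the morning. Peaks in the early night were found for *Cyp18a1*, a cytochrome P450 that inactivates moulting hormone (2.61-fold, 16.4 h ± 0.389), the cuticle protein gene *Cpr62Bb* (1.77-fold, 13.9 h), the glycolysis regulator *Pfrx* (1.67-fold, 16.5 h) and the lipase gene *dob* (1.44-fold, 15.6 h). Further called genes were *CG10237* (1.85-fold), *CG14275* (2.09-fold), *CG6409* (1.71-fold) and *CG2121*, whose probe sets gave 1.94-fold and 2.34-fold. In the 12 fits that left out 1 array, *dob* was called in 1, *CG6409* and the 2.34-fold probe set of *CG2121* in 2, *GstZ2* in 3, *CG14275* and *Pfrx* in 7 and *per* in 8.

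In all, 20 probe sets of 18 genes were rhythmic, and 15 of these probe sets peaked between 12 and 19 h and 5 between 1 and 6 h. *Cipc* was among them through 1 probe set (2.43-fold, adjusted p = 0.00895), while its brighter probe set gave 1.59-fold with an adjusted p of 0.0566. A dimmer probe set of *Ugt35B1* gave 1.13-fold and an adjusted p of 0.769. By chance 698 probe sets would have an unadjusted p under 0.05, and 1144 did. Comparisons with no called probe set exceeded 698 by more, with 2211 in DD, 1822 for the rhythm difference and 1211 for lights-on. The excess is therefore not a count of rhythms.

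**Figure D2:**
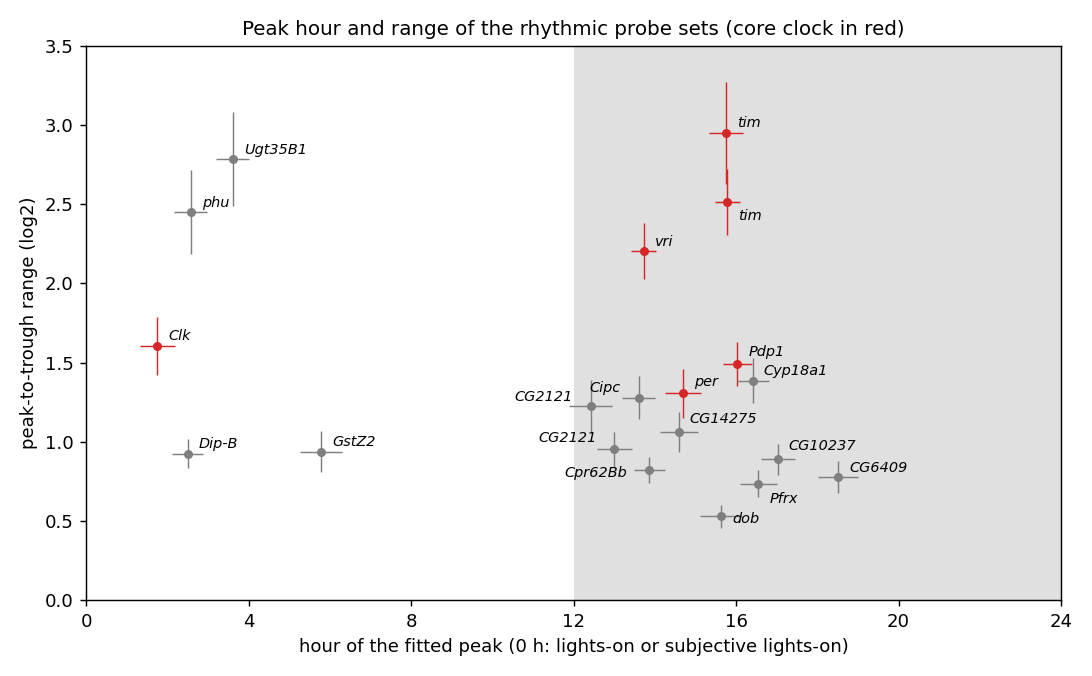
Hour of the fitted peak (horizontal, h after lights-on or subjective lights-on) against the peak-to-trough range (vertical, log2) of the 20 rhythmic probe sets. Bars are standard errors, core clock genes are red, others grey, and grey shading marks the night or subjective night. Of the 20 points, 15 lie between 12 and 19 h and 5 between 1 and 6 h.

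Among the fixed lists, calls were enriched in the core clock list (Fisher's exact test, adjusted p = 6e-10), in genes published as clock outputs of fly heads (5 called of 32, adjusted p = 1.36e-08) and in the glutathione and UDP transferases (2 called of 67, adjusted p = 0.045). The last rests on *Ugt35B1* and *GstZ2*, and *GstZ2* was called in 3 of the 12 fits that left out 1 array. Adjusted over the list alone, 18 of the 32 published outputs passed. Neither value for this list is independent evidence, since it was written from general knowledge of published clock outputs, without the literature at hand, and whether these samples were behind those publications is not given in the sources used here. In the cytochrome P450 list 1 of 81 genes passed. In the cuticle protein list 1 of 92 passed over all probe sets and 4 over the list alone, among them *Cpr49Ae* (1.73-fold, 11.3 h) and *Cpr11B* (1.58-fold, 11.5 h). *Slob*, which binds a potassium channel, passed over its list of 28 excitability channels alone with 2.58-fold and a peak at 14.8 h. The list of light repair and activity-regulated genes, which includes *tim* and *cry*, had a mean that cycled by 0.40 log2 units with an exact permutation p of 0.00412 that missed the threshold after adjustment (0.0556). Of the 24 phototransduction genes none passed.

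The count of 20 fell to 12 without the LD 6 h array and to 13 without the LD 14 h, LD 18 h or DD 14 h array. An exact permutation test of each probe set within days called none (smallest adjusted p = 0.162), with 1218 at an unadjusted p under 0.05 and 2.31e-05 as the smallest p it can give.

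In the model of both days with separate curves, the LD day showed rhythms of clock genes and of others. Of 13 probe sets called in LD, those of *per*, *vri*, *Clk*, *tim* and *Pdp1* belong to the core clock list. For *tim* this was the dimmer 5.71-fold probe set (moderated F test, adjusted p = 0.0307). The brighter 7.73-fold one did not pass in LD (adjusted p = 0.12). The LD range was 1.63 log2 units for *per*, 2.43 for *vri*, 1.89 for *Clk* and 1.67 for *Pdp1*. *t*, the hydrolase that releases histamine and dopamine from their conjugates, had a range of 1.63 ± 0.15 with a peak at 23.4 h, and *Culd*, a membrane protein of photoreceptors, had 1.52 ± 0.10 with a peak at 23.2 h. *Obp99a*, an odorant-binding protein, had 2.13 ± 0.19 with a peak at 16.2 h, and *Inos*, the first enzyme of inositol synthesis, 0.86 ± 0.10. *CG2121*, *CG3699*, *Cipc* and the deubiquitinase gene *Usp8* were the other 4, and *CG3699*, *Cipc* and *Usp8* are named after their values were seen. *Cipc* was called through its dimmer probe set, and the brighter one did not pass in LD (moderated F test, adjusted p = 0.213). *CG2121* was called through its brighter probe set, and the dimmer one did not pass (adjusted p = 0.12).

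In DD no probe set passed limma's moderated F test, whose smallest adjusted p was 0.141, although 2211 had an unadjusted p under 0.05. The fitted peaks of the clock genes in LD and DD were 15.7 and 15.8 h for the brighter probe set of *tim*, 15.3 and 13.8 h for *per*, and 13.8 and 13.6 h for *vri*. They were 16.6 and 15.4 h for *Pdp1*, and 2.41 and 0.84 h for *Clk*. The adjusted p in DD was 0.141 for *per*, *vri*, *Pdp1* and *Clk* and 0.157 for that probe set of *tim*. The moderated F test in DD gave an unadjusted p of 8.43e-05 for *vri* and *Pdp1* and 0.000282 for *Clk*. It gave 0.00031 for *per* and 0.00134 for that probe set of *tim*. DD ranges were 1.98 log2 units for *vri*, 1.35 for *Pdp1*, 1.39 for *Clk*, 1.03 for *per* and 2.62 for *tim*. No adjustment over the core clock list alone was made for DD. For 12 of the 13 probe sets called in LD the DD peak lay within 4 h of the LD peak. Chance gives 33.3% only if DD peaks are spread evenly over the day (one-sided exact binomial p = 1.69e-05, over probe sets that are not independent). With DD 6 h left out, DD 2 h was the extreme DD array for 61.1% of all probe sets, against 40% by chance. The spread of DD peaks was not tested, so this p-value does not decide whether the agreement exceeds chance. All 13 had the smaller range in DD, with medians of 1.63 log2 units in LD and 1.03 in DD, but picking them by their LD rhythm favours that direction.

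The LD count was 0 with the LD arrays fitted alone, 5 without the DD 2 h and LD 22 h arrays, 22 with the body-marker score as a covariate, and 1 without LD 2 h or DD 10 h, 2 without LD 6 h, 3 without LD 10 h or LD 14 h, 4 without LD 18 h and 6 without LD 22 h or DD 14 h. The DD count of 0 became 374 without the DD 6 h array, 1 without DD 14 h, 3 with the score and 2 without the DD 2 h and LD 22 h arrays.

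The rhythms that differed most between LD and DD, by p, were of *Culd*, *t*, *Arc1*, *stmA* and *Hdc*, although none passed. *Culd* had a range of 1.52 log2 units in LD and 0.23 in DD (SE 0.10 for each day), and *t* 1.63 in LD and 0.24 in DD (SE 0.15), each with an adjusted p of 0.224. *Hdc*, which encodes the enzyme that makes histamine, the transmitter of fly photoreceptors, had 0.64 with a peak at 22.8 h in LD and 0.35 with a peak at 16.1 h in DD. *Arc1*, a capsid-forming protein of neurons, peaked at 18.8 h in LD and at 3.95 h in DD, and *stmA*, a phosphoinositide regulator of photoreceptors, at 21.5 h and 13.8 h. The last 3 shared an adjusted p of 0.381.

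Adjusted over the list alone, the rhythm difference passed for *t* and *Hdc* among 22 genes of transmitter synthesis and transport. It also passed for *nSyb*, *Csp* and *Synj* among 15 synaptic vesicle genes, for the G protein subunit gene *Gbeta76C* among 24 phototransduction genes, and for *Hdc* and *Obp99a* among the published outputs. Among the DD arrays, DD 2 h held the lowest value of *nSyb*, *Csp*, *Synj*, *Gbeta76C* and *Hdc*, and among the LD arrays LD 22 h held the highest value of *nSyb*, *Synj*, *Gbeta76C*, *Hdc* and *t*. *nSyb* peaked at 21.1 h in LD and 13.8 h in DD, and *Gbeta76C* at 22.9 h and 12.2 h. In the male accessory gland list 5 of 15 passed in the same way. *Acp53C14a* there had a range of 3.92 log2 units in DD, where the DD 2 h array held the highest mean of that list. Of the core clock genes none passed over the list alone, and *per*, with 1.63 log2 units in LD and 1.03 in DD, had the smallest p (0.0187).

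Over all probe sets limma called 0 differences in rhythm, with 1822 at an unadjusted p under 0.05, a smallest adjusted p of 0.224, and 0 under every alternative run.

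**Figure D3:**
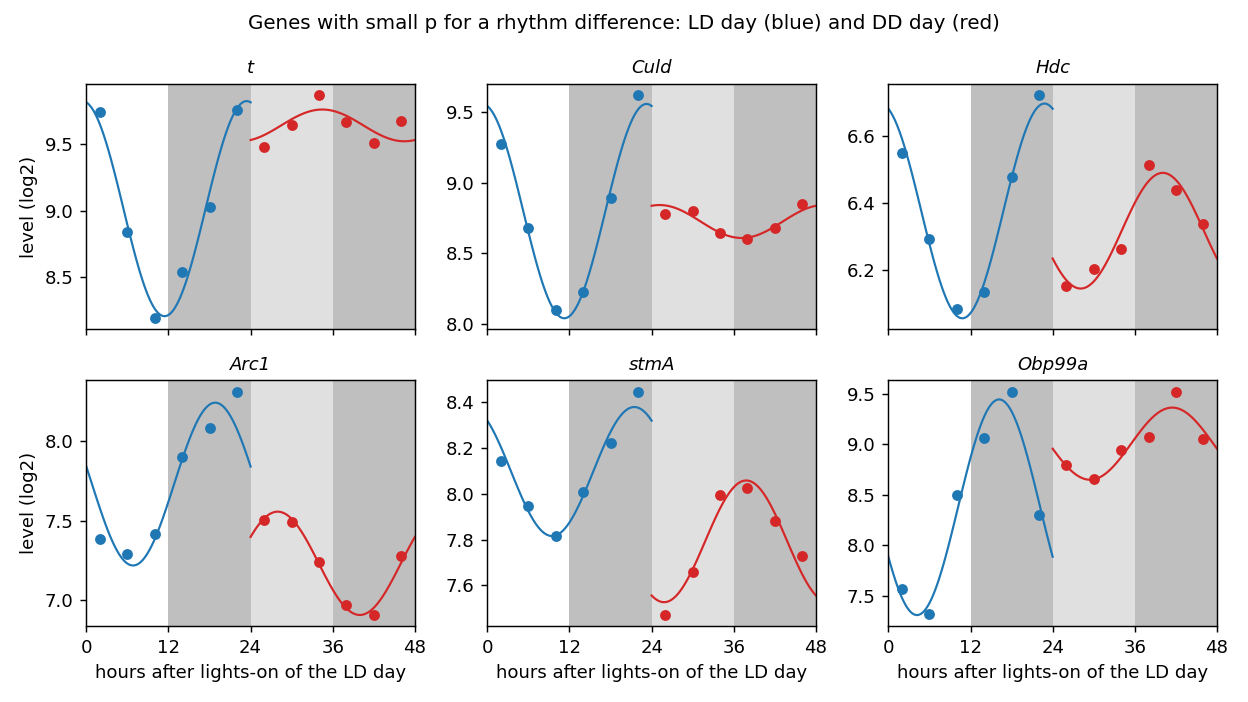
Levels (log2) of 6 genes against hours after lights-on of the LD day, 1 array per point, with a 24 h curve fitted to each day (LD blue, DD red). White is light, dark grey is night or subjective night and light grey is the subjective day in darkness. *t* and *Culd* span 1.63 and 1.52 log2 units in LD and 0.24 and 0.23 in DD.

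Between the daily means, *CG14186*, a gene known by its annotation number, was higher in LD by 0.69 ± 0.07 log2 units (7.34 against 6.66, higher at 6 of 6 hours, adjusted p = 0.0113). A probe set that names no single gene was higher by 0.61 ± 0.07 (adjusted p = 0.0212). The next genes by p did not pass: *Inos* (0.56 ± 0.08), *Tsp*, which encodes thrombospondin (0.54 ± 0.07), the cuticle gene *slf* (0.40 ± 0.06) and the photoreceptor gene *PIP82* (0.56 ± 0.08) had higher means in LD at 6 of 6 hours, with adjusted p between 0.0519 and 0.0774. *Lsp2*, a storage protein of the fat body, had a mean lower in LD by -1.30 ± 0.20 (7.61 against 8.91, adjusted p = 0.0812), and *CG8654* by -0.41 ± 0.07 (0.0829). *CG13086* (-0.27), *Ass* (-0.30) and *CG10621* (-0.47) followed with adjusted p of 0.154 to 0.159.

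At the preset correlation of camera, several lists passed. Genes of transmitter synthesis and transport were higher in LD, 21 of 22 of them, with a median of 0.15 log2 units (camera, adjusted p = 8.67e-06, and adjusted p = 0.294 with an estimated correlation). All 15 synaptic vesicle genes were higher, with a median of 0.17 (adjusted p = 0.00011, and adjusted p = 0.294 with an estimated correlation). Adjusted over the list alone, 7 transmitter genes passed, among them *VGAT*, the vesicular GABA transporter (0.27 ± 0.05), *CarT*, the carcinine transporter (0.61 ± 0.11), and *Gad1*, which makes GABA (0.35 ± 0.09). So did 4 vesicle genes, including *Rop* (0.25 ± 0.06) and *Csp* (0.27 ± 0.09). *t* was among the 7 with a lower level in LD (-0.63 ± 0.21). Thoracic flight muscle markers were higher in LD, 15 of 16, with a median of 0.33 (adjusted p = 3.67e-05, and adjusted p = 0.294 with an estimated correlation), and 6 passed over the list alone, led by the actin gene *Act79B* (0.93 ± 0.18) and by *Mlc2* (0.47 ± 0.10) and *Prm* (0.57 ± 0.12), which encode myosin light chain and paramyosin.

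The cuticle protein list was called higher in LD, with a median of 0.04 against 0.02 over all genes and 74 of 92 values above 0 (adjusted p = 0.00404, and adjusted p = 0.683 with an estimated correlation), and *Acp1* (1.80 ± 0.29), *Cpr62Bb* (0.35 ± 0.06) and *Cpr100A* (0.89 ± 0.19) were among 7 that passed over the list alone. The 9 light repair and activity-regulated genes had a median of 0.12 (adjusted p = 0.028, and adjusted p = 0.294 with an estimated correlation), with the transcription factor gene *sr* (0.34 ± 0.07) passing over the list alone. Cytosolic ribosomal protein genes were lower in LD, 30 of 37, with a median of -0.11 (adjusted p = 3.1e-05, and adjusted p = 0.107 with an estimated correlation). Their list mean was highest at DD 2 h, 6 h and 18 h (0.10, 0.17 and 0.15), the same 3 arrays on which a control probe set for 18S rRNA read highest (6.90, 8.05 and 8.24, against 4.75 to 6.48 elsewhere). Proteasome genes were lower with a median of -0.05 (adjusted p = 0.00141, and adjusted p = 0.431 with an estimated correlation), and fat body markers with a median of -0.11 (adjusted p = 0.000267, and adjusted p = 0.288 with an estimated correlation). Among the genes of lipid and carbohydrate metabolism, whose list did not pass, 8 of 47 passed over the list alone, among them the glycolytic gene *Pgk* (0.26 ± 0.06) with a higher level in LD and the storage protein gene *Lsp2* with a lower one. The 4 female markers had a median of -0.12 (adjusted p = 0.00456, and adjusted p = 0.294 with an estimated correlation).

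Markers of the gut and of male reproductive organs were lower in LD. All 34 midgut genes were lower, with a median of -0.83 (adjusted p = 9.28e-18, and adjusted p = 0.294 with an estimated correlation). All 15 male accessory gland genes were lower, with a median of -1.12, and 18 of 20 testis genes, with a median of -0.80 (adjusted p = 5.93e-13 and 5.41e-11, and adjusted p = 0.294 with an estimated correlation for both). Over the list alone 24, 11 and 13 of their members passed, for example the digestive protease gene *alphaTry* (-2.34 ± 0.77) and the seminal protein gene *Acp95EF* (-2.02 ± 0.54). The body-marker score, the mean of these 3 lists, was -0.47 ± 0.27 (SD, n = 6) in LD and 0.47 ± 0.87 in DD (exact permutation p = 0.0238 two-sided, adjusted 0.0612 over 11 marker measures). It was 1.91 on the DD 2 h array, 0.75 at DD 22 h, 0.52 at DD 6 h, 0.25 at DD 10 h, 0.14 at DD 14 h and -0.75 at DD 18 h, and lay between -0.18 and -0.77 on the LD arrays.

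**Figure D4:**
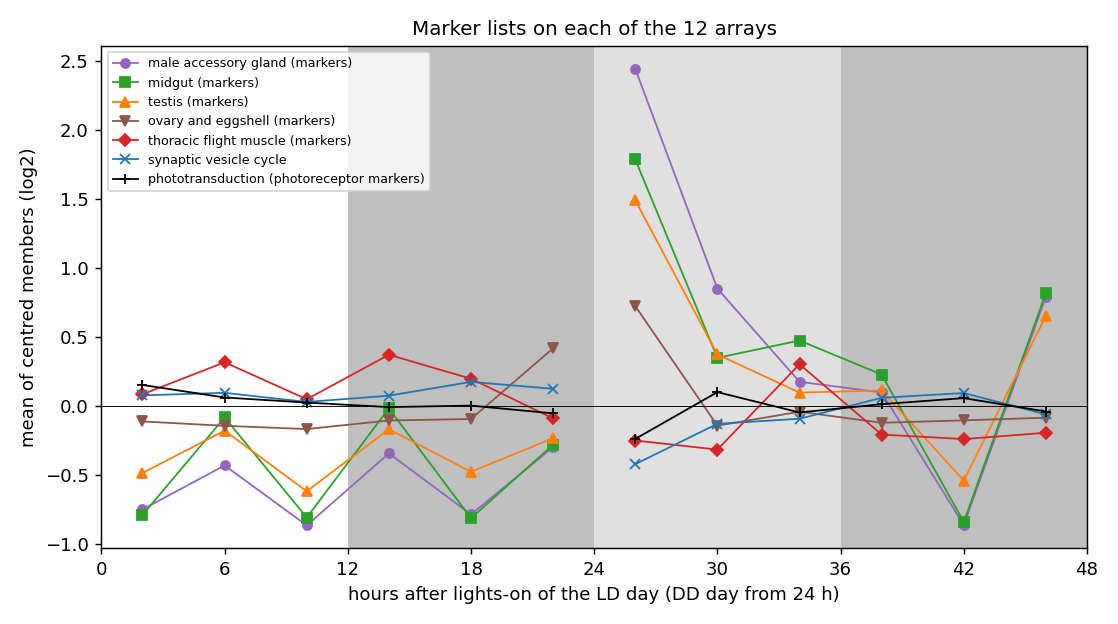
Mean of centred members (log2, vertical) of 7 gene lists against hours after lights-on of the LD day (DD from 24 h), 1 array per point, with lines joining the arrays of a day. White is light, dark grey is night or subjective night and light grey is the subjective day in darkness. On the DD 2 h array the accessory gland list stands at 2.44, the midgut list at 1.79, the testis list at 1.49 and the synaptic vesicle list at -0.42.

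Camera with its preset correlation called 12 of the 27 lists between the days, 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.0634). With the body-marker score as a covariate the preset correlation called 9 lists, 5 of them among the 12 and in the same direction. Of these 5 the ribosomal protein list also passed with fry (adjusted p = 0.0438) and had an adjusted p = 0.0284 with an estimated correlation. The flight muscle, fat body, cuticle and female lists had an adjusted p = 0.18, 0.179, 0.77 and 0.465 with an estimated correlation. The other 4 were the phototransduction, cytochrome P450, transferase and eggshell lists, with an adjusted p = 0.548, 0.465, 0.699 and 0.699 with an estimated correlation. The transmitter and vesicle lists were not called and the proteasome list turned direction. The light repair and activity-regulated list was not called either (camera, adjusted p = 0.0874), although its median stayed at 0.10 with 8 of 9 genes higher in LD. The midgut, accessory gland and testis lists make up the score, so the loss of their calls is fixed by construction. The count of 2 probe sets (1783 at an unadjusted p under 0.05) was 0 with that covariate or with the hour as a replicate block, 1 with no hour term and 6 among probe sets with a mean above the median. It was 20 without DD 10 h, 12 without LD 10 h, 1 without LD 14 h, LD 18 h, DD 2 h or DD 22 h, and 0 without LD 6 h, DD 14 h or DD 18 h.

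The light coefficient, which follows only in part how LD minus DD at the 3 lit hours departs from that at the 3 dark hours, passed for no gene. For *fit* the coefficient was 0.09, while LD minus DD was -1.49 at the lit hours and -0.99 at the dark hours. *Arc1* had the smallest p, with -1.06 ± 0.13 log2 units (adjusted p = 0.121). Its plain LD minus DD difference was -0.05 at the lit hours and 1.05 at the dark hours. The dark hours likewise carried the coefficients of *P5cr-2*, a proline synthesis enzyme (0.86 ± 0.11, with -0.05 at lit and -0.95 at dark hours), and *Cyp6g1*, a detoxifying cytochrome P450 (1.23 ± 0.21, with 0.08 and -1.14). *Ugt302C1*, a glycosyltransferase gene, had 0.86 ± 0.12, and its difference was 0.62 at the lit hours and -0.29 at the dark ones. *Lst*, the hormone limostatin, had 0.90 ± 0.13 (0.25 and -0.63), and *Glt* 0.74 ± 0.11 (0.28 and -0.48). Adjusted p was 0.121 for these genes except *Cyp6g1* (0.236).

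Negative coefficients were also measured for *Pss* (-0.54 ± 0.09), *Nazo* (-0.52 ± 0.10), the antibacterial gene *Listericin* (-0.77 ± 0.15) and *sut2* (-0.41 ± 0.09), with adjusted p of 0.196, 0.351, 0.388 and 0.486. At the lit hours their plain differences were 0.15, -0.19, -0.12 and -0.18, and at the dark hours 0.69, 0.31, 0.60 and 0.22. Adjusted over the list alone, the photoreceptor channel gene *trpl* passed among 24 phototransduction genes with 0.78 ± 0.18, and its plain differences were 0.58 at lit and -0.32 at dark hours. *Cyp6g1* passed among 81 cytochrome P450 genes, *Ugt302C1* among 67 transferases and *tws* in the core clock list (0.46 ± 0.11, with 0.32 and -0.10).

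Camera called 8 lists for this coefficient. It was positive for the published outputs (median 0.16, adjusted p = 0.0149), cytochrome P450 genes (median 0.07, adjusted p = 0.0149) and neuropeptides (median 0.11, adjusted p = 0.0083), each with an adjusted p = 0.604 with an estimated correlation. Cuticle protein genes had a median of -0.08 (adjusted p = 0.00464, and adjusted p = 0.734 with an estimated correlation), with plain LD minus DD medians of 0.01 at lit and 0.07 at dark hours. The midgut, accessory gland, testis and eggshell markers had medians of -0.73, -1.05, -0.69 and -0.29, with adjusted p of 0.604, 0.604, 0.604 and 0.698 with an estimated correlation. The DD 2 h array, where these 4 lists stood highest, was taken at an hour that is lit in LD. With fry 0 of the 27 lists passed (smallest adjusted p = 0.557), and with the body-marker score as a covariate 1 of the 8, the cuticle list, was called in the same direction (adjusted p = 0.853 with an estimated correlation). The loss of the 3 lists that make up the score is again fixed by construction. The lipid and carbohydrate list (adjusted p = 0.00646) and the proteasome list (0.0474) were newly called with the score, both with an adjusted p = 0.321 with an estimated correlation.

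Over all probe sets limma called 0 light effects, with 1211 at an unadjusted p under 0.05. The count was 1 without LD 10 h and 2 without DD 6 h.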

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

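The tests of body-part RNA and of RNA degradation on the DD 2 h array were chosen after that array was seen to stand apart, and the tests of an hour label, of probe sets rhythmic in DD and of other orders of the arrays were chosen before their results were seen.

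In each set of 6 arrays of a day, the highest or lowest array stood out when its gap to the next array, divided by the range, passed Dixon's 95% critical value for 6 samples. Of 170 sets 10 did so, and chance gives about 1 in 20, or 8.5. The LD 22 h array stood out in 5: high for the heat shock list (0.657), the eggshell markers (0.875, a mean of 0.42 against -0.10 on the next array), *jet* (0.74) and *wdb* (0.657), and low for the ribosomal protein list (0.65). The DD 2 h array stood out in 3: high for the redox list (0.65) and the eggshell markers (0.883, 0.72 against -0.04), and low in its median correlation with the other arrays (0.807). The DD 10 h array was high for the flight muscle markers (0.803, 0.30 against -0.20) and the cuticle list (0.657).

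The DD 2 h array stood apart from the other 11. On it the midgut, accessory gland, testis and eggshell lists were each higher than on any other array, by 0.306 log2 units or more, and RNA of other body parts in the head sample is a candidate explanation. A wrong hour label was argued against: the hour read from 6 clock genes lay 1 h from the label, where the largest error of the other arrays was 2.7 h. RNA degradation stays open: the mean difference of 3' and 5' control probe sets was 1.334 here and up to 1.352 on others. The control genes went different ways. For actin the difference was highest here (1.08, next 0.89), and for GAPDH it was lowest here (1.39, next 1.42). For eIF-4a it was 1.53 here and 1.59 at DD 6 h. A change of these lists in the flies themselves at that hour was not tested.

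Without the DD 6 h array 374 probe sets were called rhythmic in DD, and none with it by limma, although 2211 had an unadjusted p under 0.05 and none passed with the DD arrays fitted alone. Of the 374, 95.5% had the DD 2 h array as the extreme of the 5 remaining DD arrays, against 61.1% of all probe sets. On the 10 arrays other than DD 2 h and DD 6 h, these probe sets followed the body-marker score in the direction of their DD 2 h deviation, with a median correlation of 0.758 against -0.002 for other probe sets. This is not independent support, since the DD arrays at 10, 14, 18 and 22 h also served to call these probe sets. Also, 19 of the 91 measured midgut, accessory gland, testis and eggshell markers were among them. RNA of other body parts on the DD 2 h array may account for many of these calls, which the correlation cannot decide. A rhythm in darkness of part of these genes stays open.

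Other orders of the arrays within each day gave as many rhythmic probe sets over both days in 1 of 100, the real one, with 20 calls against at most 0. Chance is therefore an unlikely source of this count as a whole. The orders do not decide chance for single probe sets, of which the exact permutation test called none (smallest adjusted p = 0.162). For LD 2 of 100 orders, the real one included, reached 13 calls. That share is under 0.05, but the highest other order had 15 calls, more than the real one. The LD count was also 0 with the LD arrays fitted alone and 1 without LD 2 h or DD 10 h. These orders therefore do not settle chance for LD. The shift between days had 2 calls against at most 1 in the other splits, as 1 of 100, and against at most 0 in the 32 splits that swap the days within hours, a test added after the result was seen. None of the other splits reached 2 calls, but so small a count does not exclude chance. The count was 0 with the hour as a block or without LD 6 h, DD 14 h or DD 18 h. It was 1 without LD 14 h, LD 18 h, DD 2 h or DD 22 h, 12 without LD 10 h and 20 without DD 10 h. For the other 3 comparisons the real count was 0, which any order reaches (100 of 100 in DD, 32 of 32 for the rhythm difference, 100 of 100 for the light coefficient), so these counts decide nothing about chance. The highest other counts were 166, 3 and 1122. What lay behind the 166 was not tested. For the light coefficient 4 splits had over 10 calls, and 3 of these held both the LD 22 h and the DD 10 h array among their 3. Of all splits drawn, 5 held both arrays.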

How the results depend on the processing

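The body-marker score, leaving out the DD 2 h and LD 22 h arrays together, leaving out the DD 2 h array for the lists, and quantile normalization for the list shifts, were chosen after seeing the data. The 20 rhythmic probe sets became 15 to 24 with other refits and 0 with the exact test (smallest adjusted p 0.162), which cannot go below p = 2.31e-05; leaving out 1 array gave 12 (without LD 6 h) to 23 (without LD 22 h), 13 without LD 14 h, LD 18 h or DD 14 h. The 13 in LD became 0 with the LD arrays alone, which leaves fewer arrays, 22 with the score (all 13 kept) and 5 without the DD 2 h and LD 22 h arrays (2 kept). Leaving out 1 array gave 1 (LD 2 h or DD 10 h) to 14 (DD 2 h), with 2 without LD 6 h, 3 without LD 10 h or LD 14 h, 4 without LD 18 h and 6 without LD 22 h or DD 14 h. The 0 in DD became 3 with the score and 2 without those arrays, and 0 to 374 leaving out 1 (374 without DD 6 h, 1 without DD 14 h). The rhythm difference stayed at 0 in all refits. The 2 shifts between days became 6 among probe sets with a mean above the median, where fewer are tested, 1 with no hour term and 0 with the score. Leaving out 1 array gave 0 (LD 6 h, DD 14 h or DD 18 h) to 20 (DD 10 h), with 12 without LD 10 h and 1 without LD 14 h, LD 18 h, DD 2 h or DD 22 h. Lights-on stayed at 0 in other refits, with 0 to 2 leaving out 1 array (1 without LD 10 h, 2 without DD 6 h). The 1 list with a rhythm became 0 with the score taken out and stayed at 1 without DD 2 h. The 20 list shifts of both contrasts became 0 with an estimated correlation, 0 with fry, 12 with the score (3 lists in each contrast make up the score, which fixes their loss), 18 with quantile normalization and 19 without DD 2 h. Of 1259 alternative values of named genes, 1163 kept sign and side of the threshold, 82 no longer passed, 14 newly passed and 0 reversed. Ranges of rhythms and of rhythm differences are always positive and could not reverse. Peak hours were not part of this count, so its 0 reversals bear only on shifts between days and light coefficients. Where no cause is given, the cause was not tested.

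With the hour as a replicate block, which pairs LD and DD arrays of an hour, 0 probe sets shifted between days and 0 with lights-on. The alternative with a pseudocount was not run, because the values are already logarithmic. Signal over background was not measured, since the table holds no detection calls.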

Other observations

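The tests in this part, of the list shifts with the body-marker score, were chosen after the result was seen.

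The transmitter and synaptic vesicle lists were called higher in LD at the preset correlation, with adjusted p = 0.294 with an estimated correlation and 0.081 with fry for both. A larger share of RNA from other body parts in the DD samples could lower neural transcripts there. With the body-marker score as a covariate the median shift went from 0.15 to 0.0758 log2 units for the transmitter list (adjusted p = 0.115) and from 0.17 to 0.07 for the vesicle list (adjusted p = 0.374). The score itself was lower in LD (-0.47 against 0.47 in DD), so light regime and body RNA cannot be told apart for these lists. The median shift of the flight muscle markers was 0.33 without and 0.395 with the score (adjusted p = 1.26e-06, and adjusted p = 0.18 with an estimated correlation and 0.142 with fry), so it did not shrink, but body RNA stays open for this list too. Light regime, elapsed time and age stay open for both, untested.

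In LD the body-marker score was -0.23, -0.18 and -0.27 at 6, 14 and 22 h, and -0.68, -0.77 and -0.69 at 2, 10 and 18 h. Of the 20 rhythmic probe sets 10 were called in each of the 12 fits that left out 1 array, and the fewest calls were 1 for *dob* and 2 for *CG6409* and for 1 probe set of *CG2121*. The largest move of a peak hour in these fits was 0.52 h.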
